A study of Mus musculus with 20 samples.

How the data were processed

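RNA from skeletal muscle of wild-type mice was measured by poly(A)-selected, strand-directional RNA sequencing on an Illumina instrument, per the labels' protocols. The libraries fell into 4 groups of 5 by sex and training (non-trained or trained), 20 libraries in all. Other samples of the series were not analysed here. The labels used here name neither the muscle, the age of the mice, the training protocol, the time of collection nor a batch. Each library is a separate sample in the labels, but nothing ties it to a separate animal in words, so p-values measure the spread between these samples.

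The authors deposited 1 table per library with RSEM expected counts per gene, which need not be whole numbers. TPM and FPKM stand beside them in the deposited tables, per the file headers, and were not used for any test. The submitters' processing notes name the GRCm38 build, Trim Galore, cutadapt, STAR 2.5.1, RSEM 1.3.1, edgeR and limma, without saying what each did. The gene annotation release is not given in the sources used here. Of 53465 gene identifiers, 53360 matched GENCODE M21, which gave the symbols and the GRCm38 coordinates, and the unmatched identifiers held 0.00673% of the counts. RSEM divides reads that fit several genes among them by estimation, so values of near-identical gene copies are uncertain.

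Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr (minimum count 10), which left 15709 genes, and libraries were scaled by TMM. The 4 groups were fitted together with 1 coefficient per group in edgeR 4.0.16 (robust quasi-likelihood fit, 16 residual degrees of freedom before moderation) under R 4.3.3. The 6 comparisons were training in each sex, the mean of both training effects, the training by sex interaction (male effect minus female effect), and male minus female in each training state. Genes past a Benjamini-Hochberg adjusted p of 0.05 were called. Standard errors (SE) are the log2 fold change divided by the square root of its F statistic. Values in CPM, counts scaled to a common library size, use TMM-scaled library sizes, and log2 CPM values use a prior count of 2.

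The groups, comparisons, tests, gene lists, rule for named genes and alternatives given here were chosen before the data were examined, except where stated. Of 41 gene lists, 39 were tested with fry of limma 3.58.1, adjusted over the lists within a comparison, and the other 2 served as a check of sex. fry asks whether the members move, on balance, one way, while its mixed test asks whether they change in either direction, and neither compares a list with other genes or lists. camera was run with a preset correlation of 0.01 and with a correlation estimated per list. Members past the threshold were also counted with p adjusted over the list alone.

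Genes were named by a fixed rule. For training in each sex and for sex in non-trained mice it took up to 10 higher and 10 lower genes with the largest change among those past the threshold. A mean of at least 1 CPM and no overlap between the 5 and 5 libraries were required. For the other comparisons it took up to 5 and 5, without the overlap condition for the mean (which needed the same sign in both sexes) and the interaction. Predicted genes, clone names, immune receptor segments, pseudogenes, Y-linked genes and Xist were left out. Where no gene allowed by the rule passed, the 3 higher and 3 lower genes with the smallest unadjusted p were taken, and up to 4 members of each described list were added by the smallest unadjusted p. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

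The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library size without TMM, no low-count filter, a stricter filter (at least 1 CPM in at least 5 libraries and a mean of at least 20 counts), only the groups compared in the fit, removal of mitochondrial DNA genes and the 20 highest genes, and each library left out in turn. Leaving out female non-trained library 1, alone for every comparison or together with male non-trained library 5, and leaving out male non-trained library 5 with male trained library 1, were added after the data were seen. The last pair was picked for resembling the other training group, so its counts are no evidence of training. The median of each list with 1 library left out was also added then. A list of fatty acid synthesis genes was also written after the data were seen. The criterion for whether 1 library carried that list in males was tightened after its value was seen, to ask for a 95% interval, because the value lay at the bound first written. The group labels were also redrawn in 100 splits, the real one included.

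Each library held 22043145 to 38483572 counts. The procedure was tested on simulated counts for training in females, with 15436 genes left after the filter. It recovered 39 of 98 of these genes changed 1.5-fold (39.8%) and 70 of 99 changed 2-fold (70.7%), and called 9 unchanged genes. The simulated genes varied independently of each other and no library was made to stand apart, so recovery in the real libraries may differ. Replicate pairs differed by 21.0 to 188 times the variance that counting alone gives, over genes with more than 100 counts in the pair, so no pair looked like a library entered again.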

Results

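Gene expression was measured in skeletal muscle of wild-type mice that differed in sex and training, with 5 libraries in each of 4 groups: non-trained females, trained females, non-trained males and trained males. The title of the series concerns exercise, mitochondrial remodelling and age-associated decline, and the comparisons ask what training changed in each sex, whether the sexes differed in that, and how the sexes differed in each training state. Library totals ran from 22043145 to 38483572 counts. Genes encoded in mitochondrial DNA took 11.2% to 15.9% of the counts.

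The sex markers matched the labels in every library. Xist, the X inactivation transcript, stood at 161.5 ± 16.4 CPM (SD, n = 10) in female libraries and at 9.62 CPM or less in male libraries. Ddx3y, a Y-linked helicase gene, stood at 92.2 ± 4.63 CPM (SD, n = 10) in male libraries and at 1.33 CPM or less in female libraries. The first principal component of log2 CPM held 22% of the variance and placed all 10 male libraries above all 10 female libraries. The second held 10.5% and set female non-trained library 1 (64.8) far from the others, the next highest being 16.7. That library had the highest total (38483572 counts) and the fewest genes above 0 (18727, against 19806 to 21449 elsewhere).

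In non-trained mice, male muscle had higher expression of 4 genes of polyamine metabolism, 3 of synthesis and 1 of breakdown. Amd1 (chromosome 10, 40287458 to 40302186), which encodes S-adenosylmethionine decarboxylase, stood at 1617 ± 278 CPM in males and 280.5 ± 45.1 CPM in females (SD, n = 5 each), a log2 difference of 2.53 (SE 0.17, adjusted p = 7.4e-09). Odc1, encoding ornithine decarboxylase, was higher by 1.51 (SE 0.19), Smox, encoding spermine oxidase, which breaks spermine down, by 2.05 (SE 0.33) and Amd2 by 2.53 (SE 0.42), each past the threshold. Amd2 is a close copy of Amd1, so reads shared between them could inflate its value. Of the 10 measured polyamine metabolism genes, 4 rose, none fell and 6 did not pass, or 5 rose adjusted over the list alone. The list was higher in males by fry (adjusted p = 3.6e-07) and by camera (adjusted p = 0.035 with an estimated correlation).

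**Figure D1:**
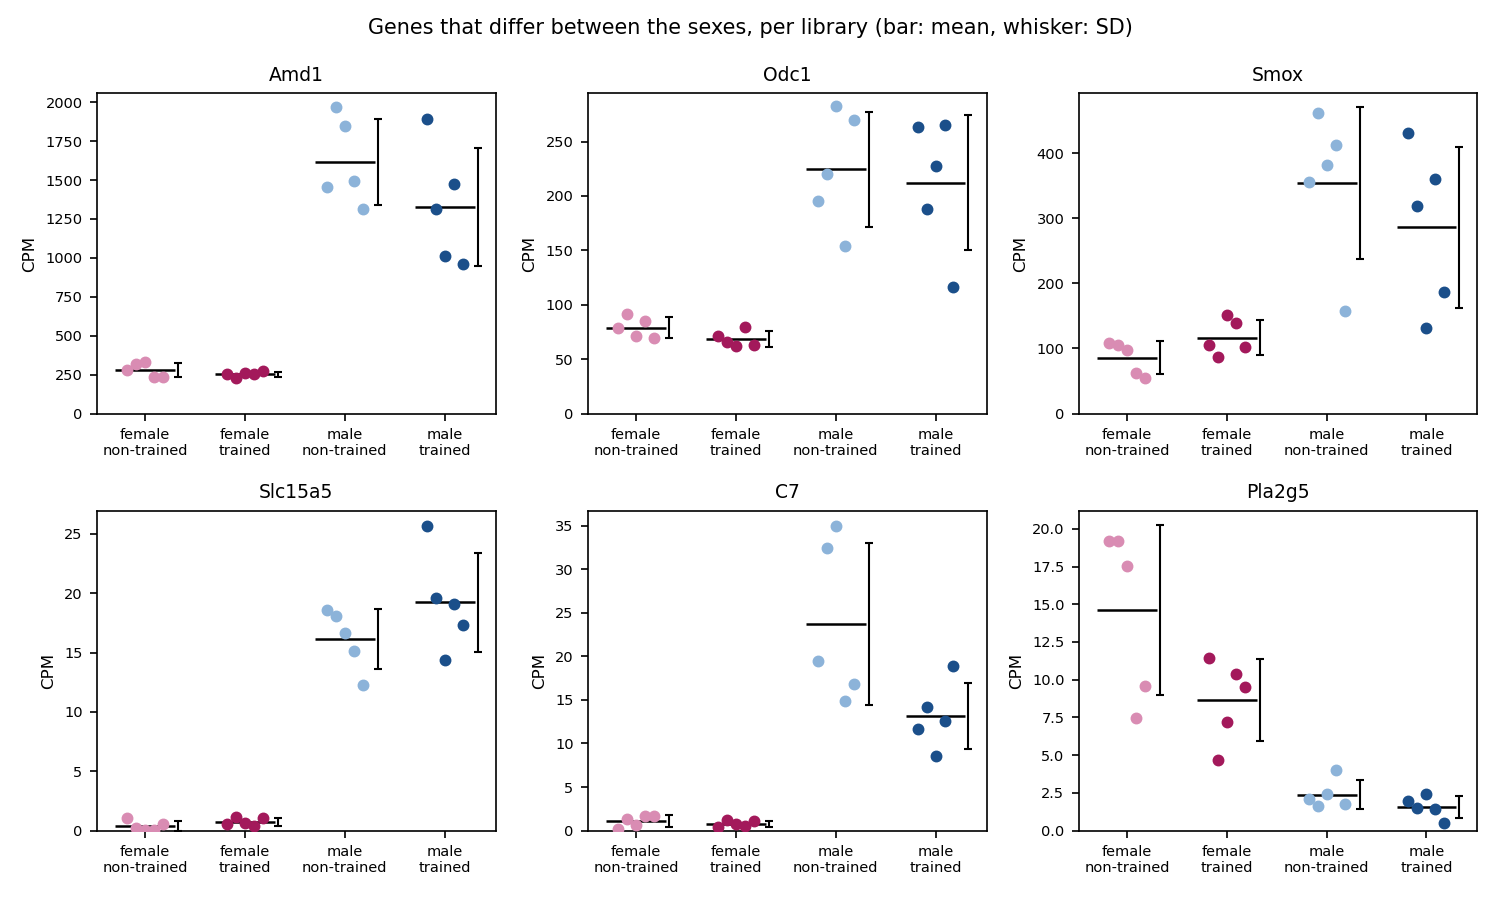
CPM of 6 genes in each of the 20 libraries, with points for libraries, bars for group means and whiskers for the SD (n = 5). Amd1 averaged 1617 CPM in non-trained males and 280.5 CPM in non-trained females, and Slc15a5 and C7 were near 0 in females while Pla2g5 was higher in them.

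Among genes whose 5 male and 5 female libraries did not overlap and that met the rest of the naming rule, the largest higher genes in non-trained males were Slc15a5 (chromosome 6, 137983586 to 138079916), a predicted peptide transporter gene, at 16.2 ± 2.55 against 0.377 ± 0.430 CPM in females (SD, n = 5 each), and C7 (chromosome 15, 4988762 to 5063740), a complement component gene, at 23.7 ± 9.34 against 1.10 ± 0.646 CPM. Irx3os, Cacna2d4, Npnt, Slc30a2, Mchr1, Fscn2 and Amd1 followed with log2 differences from 3.25 (Irx3os) down to 2.53 (Amd1). By the same rule the largest lower genes were Mup22, a major urinary protein gene of a multigene family, at 0.0429 ± 0.0958 against 5.36 ± 4.57 CPM, and Tnnc1, the slow troponin C gene, at 20.4 ± 14.1 against 157.9 ± 69.1 CPM. Pla2g5, Rspo3, Mettl21e, Kazald1, Ak4, Mybph, Tmem266 and Ces1d followed, from -2.62 (Pla2g5) to -1.33 (Ces1d). Mup22 was at 0 in 4 of the 5 non-trained males, and reads of its family cannot be assigned with certainty.

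Slow fibre genes were lower in non-trained males. Myh7, the slow myosin heavy chain gene, stood at 189.9 ± 143 against 1410 ± 611 CPM in females (SD, n = 5 each), a log2 difference of -2.89 (SE 0.66), and Tpm3 and Tnni1 differed by -2.30 and -2.83. Of 18 slow fibre genes, 6 fell, 12 did not pass and 15 fell adjusted over the list alone. Macrophage markers were higher: 6 of 10 rose, all 10 adjusted over the list alone, among them Cd163 (1.32), Lyz2 (1.58) and Csf1r (1.39). The list of mitochondrial biogenesis and mitochondrial DNA maintenance was lower with a median of -0.16, with 1 of 25 members past the threshold, Twnk (-0.34), the mitochondrial helicase gene. fry gave adjusted p = 0.035 for slow fibre genes, 0.018 for macrophage markers and 0.018 for mitochondrial biogenesis. All 3 calls were lost with an estimated correlation (adjusted p = 0.54, 0.54 and 0.43) and without female non-trained library 1 (adjusted p = 0.10, 0.067 and 0.067). The slow fibre mean of female non-trained library 3 (5.41 log2 CPM) lay below the other 4 of its group (6.84 to 7.18).

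Of 39 lists, 4 passed fry, the polyamine, slow fibre, macrophage and mitochondrial biogenesis lists. Of 6 erythroid markers 2 rose, the list did not pass (adjusted p = 0.16), and Hbb-bs stood at 1688 CPM in male non-trained library 4 against 103 to 502.5 CPM in the other 4 of its group. edgeR called 818 of 15709 genes between the sexes in non-trained mice, 493 higher and 325 lower in males. With library size alone the share of higher calls moved from 60.3% to 75.0%. The count fell to 435 without male non-trained library 3, 499 without male non-trained library 2 and 507 without female non-trained library 2. It rose to 1007 without female non-trained library 5 and to 1465 with DESeq2. Rspo3 lost its call without male non-trained library 3 (adjusted p = 0.052), while limma-voom did not call Irx3os, Mup22 or Rspo3.

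In trained mice the same 4 polyamine genes were higher in males: Amd1 by 2.39 (SE 0.17, adjusted p = 1.9e-08), Odc1 by 1.64 (SE 0.19), Amd2 by 2.98 (SE 0.42) and Smox by 1.29 (SE 0.32). Of 10 members 4 rose and 6 did not pass, or 6 rose adjusted over the list alone, with adjusted p = 1.8e-07 by fry and 0.0072 with an estimated correlation. Amd2 stood at 59.49 CPM in male trained library 5, against 10.56 to 26.71 CPM in the other trained males, while Amd1 was lowest in that library (960.6 CPM). Reads shared with Amd1 could inflate Amd2 here too. Clock genes moved in both directions: 5 of 19 rose, among them Dbp (2.12), Tef (0.51) and Cry2 (0.52), and Arntl, the Bmal1 gene, fell by 1.01. The labels do not give the time of collection, with which clock genes vary. The list did not pass as a whole in one direction (adjusted p = 0.21 by fry) but did when either direction counted (adjusted p = 0.00039 by fry), as did 10 of the 39 lists in all. Of 10 macrophage markers 6 rose, among them Fcgr1 (2.65) and Cd68 (2.18), and the list did not pass (adjusted p = 0.062, and 0.64 with an estimated correlation), though it did without female non-trained library 1 (adjusted p = 0.038). Cd68 stood at 27.61 CPM in male trained library 3, against 4.675 to 7.961 CPM in the other trained males. The macrophage mean of that library was 5.31 log2 CPM, against 3.03 to 4.15 in the others of its group. Schwann cell markers had a median of -1.17, with 1 of 9 past the threshold and 7 lower adjusted over the list alone, and that list did not pass (adjusted p = 0.21). Musk, the kinase gene of the neuromuscular junction, was higher by 1.85 (SE 0.15). By the naming rule Slc15a5, C7, Cacna2d4, Slc30a2 and Amd2 were the largest higher genes, from 4.65 (Slc15a5) to 2.98 (Amd2). Mup22, Pla2g5, Mybph, Ces1d and Ostn were the largest lower genes by that rule, from -4.17 (Mup22) to -1.81 (Ostn).

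edgeR called 880 genes between the sexes in trained mice, 532 higher and 348 lower in males. With library size alone the share of higher calls moved from 60.5% to 79.6%. The count fell to 494 without male trained library 3, 578 without female trained library 4 and 582 without male trained library 2. It rose to 1401 with DESeq2. The trained and non-trained comparisons contrast different libraries. The fit takes each gene's spread from all 20 libraries, however, so their calls are not independent. The comparisons shared 262 higher and 149 lower genes, and no gene was called in opposite directions. Independent calls would share 16.7 and 7.2 by chance, which may be too low here.

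Training in females gave no gene past the threshold in edgeR. At an unadjusted p under 0.05 there were 1347 genes, where independent genes would give 785 by chance and 29 of 100 splits of the libraries gave as many or more. DESeq2 called 33, including all 6 genes named next, and limma-voom 0. The genes with the smallest unadjusted p, none of which passed in edgeR, were Kcng4, a potassium channel gene, at 24.6 ± 4.81 CPM in trained and 11.9 ± 2.45 CPM in non-trained females (SD, n = 5 each; log2 difference 1.06, SE 0.20, adjusted p = 0.27), Cnp (0.85) and Akr1b10 (0.43), and on the lower side Rbm24 (-0.35), Dusp27 (-0.41) and Strn3 (-0.24). All 22 genes of the TCA cycle list had values above 0 with a median of 0.23, none passed over all genes and 12 passed adjusted over the list alone, led by Sdha (0.32), Idh3g (0.26), Cs (0.24) and Mdh2 (0.29). Schwann cell markers had a median of 1.09, with Prx at 1.09, and adipocyte markers a median of 0.87, with Cfd at 1.45. The Schwann cell mean of female non-trained library 1 was 0.259 log2 CPM, below the other 4 of its group (1.85 to 2.40), and without it the median was 0.88. None of the 39 lists passed fry, and the TCA cycle, Schwann cell and adipocyte lists had an adjusted p of 0.27 each, or 0.61 with an estimated correlation.

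Training in males also gave no gene past the threshold in edgeR, with 676 genes at an unadjusted p under 0.05, below the 785 expected. DESeq2 called 5, Cyp1a1 among them, and limma-voom 0. Without male non-trained library 5, edgeR called 1 gene, Dynlt1b (log2 difference 0.93, adjusted p = 0.018), named after its value was seen. The genes with the smallest unadjusted p were Cyp1a1, a cytochrome P450 gene, at 3.36 ± 1.37 CPM in trained and 1.17 ± 0.142 CPM in non-trained males (SD, n = 5 each; log2 difference 1.52, SE 0.31, adjusted p = 0.73), Met (0.40) and Zmym6 (0.45), and on the lower side Arntl (-0.80), Epha7 (-0.82) and Sat2 (-0.75). Arntl is a clock gene and the labels do not give the time of collection, so a difference in time cannot be told apart from training in males. All 6 erythroid markers had values below 0 with a median of -2.08, and 6 passed adjusted over the list alone. Without male non-trained library 4 the median was -0.97. Hbb-bs averaged 536.3 ± 662 CPM in non-trained and 134.1 ± 23.6 CPM in trained males (SD, n = 5 each), with 1688 CPM in male non-trained library 4. In the slow fibre list 16 of 18 genes had values above 0 with a median of 0.56, and the list mean was 5.08 ± 0.692 log2 CPM in non-trained and 5.79 ± 0.428 in trained males (SD, n = 5 each; adjusted p = 0.66 by fry, and 0.63 with an estimated correlation). Without male non-trained library 4 the slow fibre median was 0.93. None of the 39 lists passed fry (adjusted p = 0.53 for erythroid markers, and 0.63 with an estimated correlation).

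Averaged over the sexes, training gave small positive values across mitochondrial energy genes that did not pass as lists. In the TCA cycle list 22 of 22 genes, in the ATP synthase list 17 of 17 and in the list of respiratory complexes II to IV 28 of 28 had values above 0, with medians of 0.18, 0.19 and 0.20. None passed over all genes in edgeR, and 17, 13 and 19 passed adjusted over the list alone. DESeq2 called Atpif1 over all genes (log2 difference 0.33, adjusted p = 0.0327). Idh3g (0.20), Sdha (0.23), Atpif1 (0.33), Atp5b (0.25) and Uqcrc1 (0.22) were among the leading members. All 36 genes of complex I had values above 0 with a median of 0.16, and none passed either way. fry gave adjusted p = 0.098, 0.098, 0.14 and 0.25 for these 4 lists, and camera with an estimated correlation gave adjusted p = 0.48, 0.48, 0.48 and 0.58. Slow fibre genes had values above 0 in 14 of 18 cases with a median of 0.33, or 0.21 without female non-trained library 3 (adjusted p = 0.78 by fry, and 0.89 with an estimated correlation). The TCA cycle mean of male trained library 3 (7.92 log2 CPM) lay below the other 4 of its group, and so did that of female non-trained library 3 (7.94). The list of the mitochondrial stress response had the smallest adjusted p by fry (adjusted p = 0.060, and 0.39 with an estimated correlation).

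**Figure D2:**
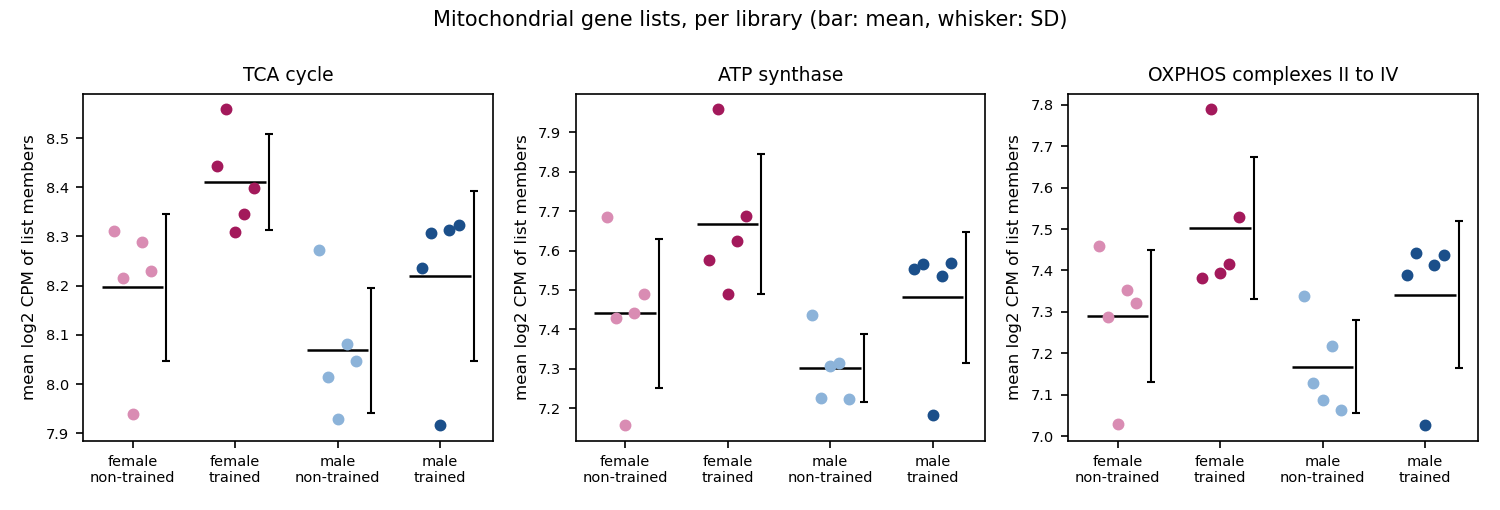
Mean log2 CPM over the members of 3 mitochondrial lists in each of the 20 libraries, with points for libraries, bars for group means and whiskers for the SD (n = 5). The TCA cycle mean was 8.20 in non-trained and 8.41 in trained females, and 8.07 in non-trained and 8.22 in trained males, with libraries of the groups overlapping.

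For the mean of both sexes edgeR called 2 genes, both lower in trained mice, with 1441 genes at an unadjusted p under 0.05. DESeq2 called 30, including the 6 genes of the rule, and limma-voom 0. The 2 genes, named after their values were seen, were Gm17167 (chromosome 4, 42206998 to 42235313; -3.03, adjusted p = 0.016) and Gm13301 (chromosome 4, 42216908 to 42235604; -4.36, adjusted p = 0.029). They overlap each other in the annotation and have near-identical copies nearby, so their separate values are uncertain. No gene was called without female non-trained library 3, female trained library 1, female trained library 2, male non-trained library 4 or male trained library 4, 1 was called without any 1 of female non-trained libraries 4 and 5, female trained libraries 3 and 4, male non-trained libraries 2 and 3 and male trained library 3, and 7 were called without male non-trained library 5. Of the 20 fits with 1 library left out 15 called Gm17167 and 6 called Gm13301, which was lost without any 1 of female non-trained libraries 3, 4 and 5, female trained libraries 1 to 4, male non-trained libraries 2, 3 and 4 and male trained libraries 1, 3, 4 and 5, and also without a low-count filter. The summed level of these genes and 2 neighbours was 0.734 CPM in male non-trained library 5, within the range of the trained libraries. The genes of the rule, none of which passed in edgeR, were Fasn, the fatty acid synthase gene (2.58, SE 0.52, adjusted p = 0.17), Pla2g16 (0.30) and Mgst1 (0.53), and on the lower side Hes1 (-0.94), Rbm24 (-0.25) and Eif5 (-0.20). Hes1 passed without male non-trained library 5 (adjusted p = 0.042). Fasn stood at 179.2 ± 122 CPM in trained and 30.9 ± 21.4 CPM in non-trained females, and at 171.8 ± 262 CPM in trained and 27.9 ± 5.21 CPM in non-trained males (SD, n = 5 each). Its log2 difference was 1.76 without male trained library 5, in which it stood at 639.4 CPM. Adipocyte markers had a median of 0.36, or 0.06 without male trained library 5 and 0.55 without female non-trained library 5, with 2 of 10 past the threshold adjusted over the list alone, and did not pass (adjusted p = 0.70).

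**Figure D3:**
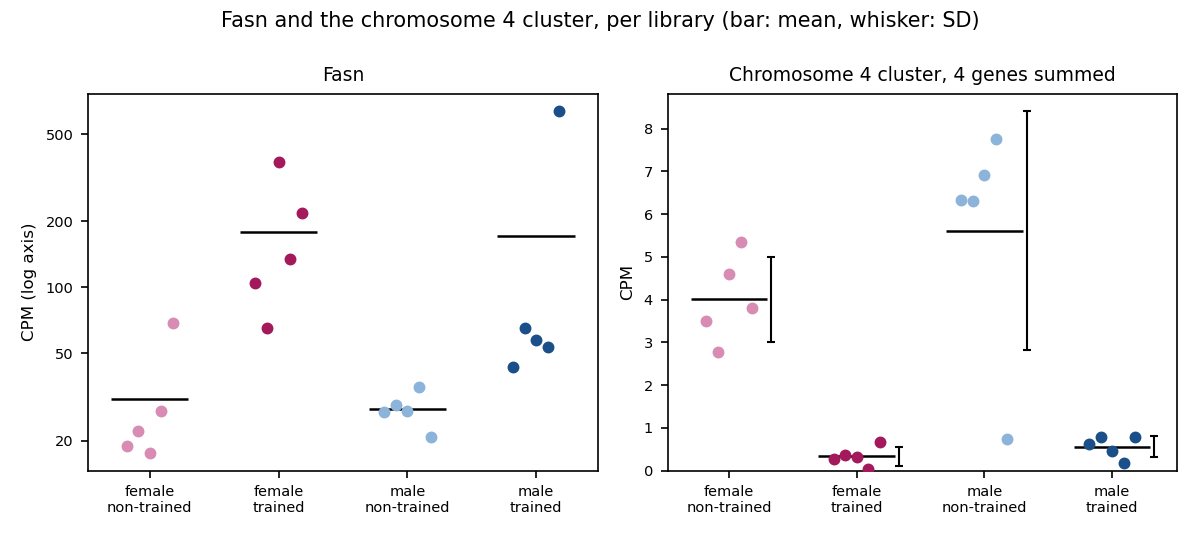
CPM of Fasn on a log axis and the summed CPM of 4 predicted genes of a chromosome 4 cluster in each of the 20 libraries, with points for libraries, bars for group means and, in the cluster plot, whiskers for the SD (n = 5). Fasn reached 639.4 CPM in male trained library 5, and the cluster sum of male non-trained library 5 (0.734 CPM) lay among those of the trained libraries.

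The training by sex interaction gave no gene past the threshold in edgeR, with 656 genes at an unadjusted p under 0.05. DESeq2 called 1, Strn3, and limma-voom 0. The genes with the smallest unadjusted p, none of which passed (adjusted p = 0.999 each), were Strn3 (0.30), Pcm1 (0.42) and Cyp1a1 (1.67), and on the lower side Kcng4 (-1.15), Trim11 (-0.61) and Cldn19 (-2.37), a claudin gene. Schwann cell markers had a median of -1.80, with 8 of 9 lower adjusted over the list alone, and did not pass fry (adjusted p = 0.90, and 0.89 with an estimated correlation). The Schwann cell mean of female non-trained library 1 (0.259 log2 CPM) lay below the other 4 of its group (1.85 to 2.40). Across genes, which are not independent replicates, the training effects in females and males correlated with Pearson's r of 0.114 and Spearman's rho of 0.122, and 56.1% of genes had the same sign.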

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

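The tests of the chromosome 4 cluster's copy-number explanation, of adipose tissue and of the Y-linked reads were chosen after the values were seen, and so was the final criterion of the test of male trained library 5, while the others were written before their results.

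A library was set apart where its gap to the nearest of its group exceeded 0.71 of the group's range. Of 336 such tests 29 did so, where chance gives about 16.8. Male trained library 3 had the lowest mean log2 CPM of its group for complex I (6.42), complexes II to IV (7.03), ATP synthase (7.18), the TCA cycle (7.92) and mitochondrial dynamics (6.24), and the highest for the ageing and inflammation list (3.41). Female non-trained library 1 was highest for mitochondrial import and cristae (5.38) and lowest for fibroblast markers (3.43) and Schwann cell markers (0.259). Female non-trained library 3 was lowest for the TCA cycle (7.94) and slow fibre genes (5.41). Female trained library 2 was highest for the interferon response (3.12) and the cytosolic ribosome (7.01), and lowest for fibroblast markers (4.84) and Pcm1 (44.8 CPM). Female trained library 1 was lowest for the ageing and inflammation list (1.63). Male non-trained library 1 was highest for mitochondrial dynamics (6.39), smooth muscle markers (5.40) and Mup22 (0.214 CPM, the other 4 at 0). Male non-trained library 4 was highest for neutrophil markers (1.38), of which 3 of 8 listed were measured. Male non-trained library 5 was highest for skin markers (2.17), of which 2 of 8 listed were measured. Male trained library 5 was highest for the mitochondrial stress response (4.42), Fasn (639.4 CPM) and Ak4 (8.44 CPM). Arntl was lowest in male non-trained library 5 (14.9 CPM), Rbm24 in female non-trained library 5 (167.5 CPM) and Zmym6 in female non-trained library 2 (6.75 CPM). Fasn was highest in female non-trained library 5 (68.7 CPM) and Eif5 in female trained library 4 (204.7 CPM).

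The first pattern is a cluster of 4 predicted genes on chromosome 4 (42206998 to 42242685), Gm17167, Gm13301, Gm5859 and Gm10600, chosen after their values were seen. Their summed CPM was 0.775 or less in all 10 trained libraries and at least 2.77 in 9 non-trained libraries, but 0.734 in male non-trained library 5. Redistribution of reads to the 26 other predicted genes within 500 kb is argued against, because these changed by -3.88 CPM (95% interval -5.93 to -1.83) where a gain of 4.37 was needed. Nearby genes with other kinds of names, copies elsewhere and discarded reads were not examined, so redistribution to them stays open. A wrong label on male non-trained library 5 stays open. Of 226 genes chosen without it at an unadjusted p under 0.01, 80.5% lay nearer the trained mean in it, against at most 62.2% in the other non-trained males. However, male trained libraries 1 and 3 had 72.2% and 64.4% nearer the non-trained mean. Single genes, chosen after their values were seen, went both ways. The Fasn level of male non-trained library 5 (20.7 CPM) was below that of all trained males. Its Entpd4 level (68.47 CPM) was below the other non-trained males (129.3 to 139.3 CPM) and within the range of trained males (62.41 to 158 CPM). Its Aacs level (7.118 CPM) was above the other non-trained males (3.763 to 4.258 CPM) and within the range of trained males (3.42 to 14.28 CPM). Training in males gave no gene past the threshold in edgeR, so the chosen genes are not shown to follow training. An inherited copy-number difference between the mice may also be the source and cannot be told apart from training here, because no DNA was measured.

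The second pattern is in a list of 17 fatty acid synthesis genes written after the values were seen, whose mean log2 difference between trained and non-trained mice was 0.95 in females (95% interval 0.33 to 1.58) and 0.59 in males (95% interval -0.13 to 1.31). No member passed in either sex (smallest adjusted p = 0.37 in females and 0.99 in males by edgeR), and fry of limma gave an unadjusted p of 0.0065 in females and 0.074 in males. For the mean of both sexes fry gave an unadjusted p of 0.0026, and the smallest adjusted p by edgeR was 0.17. DESeq2 called Fasn (adjusted p = 0.00028), and also Slc25a1 (0.00146), Elovl6 (0.00565), Aacs (0.0106), Acly (0.0205) and Thrsp (0.0205), picked after their values were seen. With male trained library 5 left out, edgeR called Slc25a1 for the mean (log2 difference 1.31, adjusted p = 0.025), which it did not with all libraries. Carried-over adipose tissue remains a candidate explanation in females, where 9 adipocyte markers outside the list were higher by 0.89 (95% interval 0.13 to 1.65), with Cfd at 85.3 against 31.2 CPM, Fabp4 at 168.2 against 127 CPM and Plin4 at 321 against 277.1 CPM, all of them also detected in non-trained muscle. In males these markers differed by -0.59, but the interval (-2.03 to 0.86) includes the list's own difference, so adipose tissue cannot be told apart there. Male trained library 5, with Fasn at 639.4 CPM, also had the highest mean of the full adipocyte list among trained males (5.34 log2 CPM, against 2.61 to 4.61). Without male trained library 5 the male difference was 0.30 (95% interval 0.04 to 0.55; unadjusted fry p of 0.21), too wide to say whether that library carries it, and an effect of training itself stays open and untested.

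The third pattern is reads of Y-linked genes in female libraries. Ddx3y, Eif2s3y, Kdm5d and Uty summed to 70 counts in female non-trained library 5 and 83 in female trained library 2, which is 1.59% and 1.78% of the male level, against at most 0.218% in the other female libraries. Carry-over from male libraries is consistent with these counts, since the 4 genes kept the male ratio within counting error (Monte Carlo chi-square p = 0.145 and 0.148). No biological explanation was tested.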

How the results depend on the processing

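The settings that leave out named pairs of libraries, or female non-trained library 1 in every fit, were chosen after the data were seen. DESeq2 called 33 genes for training in females, 5 in males, 30 for the mean, 1 for the interaction, and 1465 and 1401 for sex in non-trained and trained mice. limma-voom called 0 for the mean. Without a low-count filter 1 gene was called for the mean and 558 for sex in trained mice, with more genes tested. With only the groups compared in the fit, 448 were called for sex in non-trained mice. With 1 library of the groups compared left out, counts ranged from 0 to 0 for training in females, 0 to 1 in males, 0 to 7 for the mean, 0 to 0 for the interaction, 435 to 1007 for sex in non-trained mice and 494 to 818 in trained mice. Leaving female non-trained library 1, of neither group compared, out of the fit raised the count for sex in trained mice from 880 to 1239. Without female non-trained library 1 and male non-trained library 5, 1 gene was called for training in males, 8 for the mean, 434 for sex in non-trained mice and 1223 for sex in trained mice. Without male non-trained library 5 and male trained library 1, 10 and 21 were called for training in males and the mean. These males were picked because they resembled the other training group, so higher counts follow from the choice and are no evidence of a training effect. camera with the preset correlation called 12, 16, 10, 8, 21 and 17 lists in the 6 comparisons, in the order training in females, in males, mean, interaction, sex in non-trained and in trained mice. For sex in non-trained mice 1 list was called with an estimated correlation, 2 with library size only, 1 without female non-trained library 1 and 1 without each pair. For sex in trained mice 3 were called with library size only, 2 without female non-trained library 1 and 2 without it and male non-trained library 5. The cause of these differences was not tested. Named genes were tested again with DESeq2, limma-voom, RLE size factors, library size only, no low-count filter and each library left out, and not under the other settings. Of these 930 tests, 903 kept their side of the threshold and their direction, 12 lost the call, 15 gained it (14 in DESeq2) and 0 reversed. Among the lost calls, limma-voom ended those of Irx3os, Mup22 and Rspo3 between the sexes.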

Other observations

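The tests on other splits of the libraries were set before their results were seen, and the single genes of the last paragraph were chosen after.

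Single members of 3 further lists also differed between the sexes. Musk was higher in males by 1.28 in non-trained and by 1.85 in trained mice, and Myh8, the perinatal myosin heavy chain gene, by 1.31 in trained mice. In the denervation and neuromuscular junction list 1 of 27 and 2 of 27 genes rose, and the list passed when either direction counted (adjusted p = 0.00067 and 9.6e-11 by fry of limma). Of the 39 lists, 9 in non-trained and 10 in trained mice passed in this way, so such a pass is not particular to the lists named here. In the atrophy and proteolysis list of 25 genes 4 were lower in trained males, among them Klf15 (-0.78), Foxo3 (-0.53) and Ppp1r3c (-0.77), a glycogen-targeting phosphatase subunit gene, or 5 adjusted over the list alone. That list passed when either direction counted (adjusted p = 0.00039) and not in one direction (adjusted p = 0.23). In the ageing, senescence and inflammation list of 23 genes 3 were higher in non-trained males, the complement genes C3 (1.29) and C4b (1.58) and the chemokine gene Ccl8 (3.79), or 5 adjusted over the list alone, and the list did not pass in one direction (adjusted p = 0.077).

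Redrawing the labels in 100 splits, the real one included, asked what chance gives. For sex, 1 split, the real one, reached 818 genes in non-trained mice (highest other 1) and 1 reached 880 in trained mice (highest other 2), so chance can be excluded. For lists, 1 split, the real one, reached 4 lists in non-trained mice (highest other 1) and 3 reached 1 list in trained mice (highest other 1). Both shares lie under 0.05 but were not adjusted for the number of split tests. Other splits also reached the 1 list of trained mice, so chance is not excluded there. For training, 100 of 100 splits reached the 0 genes seen in females, in males and for the interaction (highest other 3, 9 and 3), which any split does against a count of 0, so this tests nothing. At an unadjusted p under 0.05, 29 splits reached the 1347 genes of females (highest other 2110), 26 the 676 of males (highest other 1385) and 56 the 656 of the interaction (highest other 1537), so chance cannot be excluded for these counts at an unadjusted p. For the mean of both sexes, 2 splits reached the 2 genes (highest other 3) and 3 reached 1441 genes at an unadjusted p under 0.05 (highest other 1767). The correlation across genes of the female and male training effects, 0.114, was reached by 4 splits (highest other 0.119). These 3 shares lie under 0.05, but they were not adjusted for the number of split tests, and another split exceeded each result. Chance is therefore not excluded for them. The splits do not exclude an inherited difference between the mice for the 2 genes. limma-voom called neither, and of 20 fits with 1 library left out, 15 called Gm17167 and 6 called Gm13301.

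Xist was at 6.09 to 9.62 CPM in 5 of 10 male libraries and at 0.527 CPM or less in the other 5, with full Y-linked expression in all 10. The higher values are 3.77% to 5.96% of the female mean, and the lower ones 0.327% or less. The higher shares exceed the Y-linked shares of female non-trained library 5 and female trained library 2 (1.59% and 1.78%). Carry-over from female libraries was not tested for Xist and stays open. Per2 stood at 30.2 CPM in male non-trained library 5, against 6.54 to 15.7 CPM in the other non-trained males and 18.8 to 26.04 CPM in trained males. Nr1d1 stood at 47.66 CPM in that library, against 123.6 to 157.6 CPM in the other non-trained males and 63.03 to 104.4 CPM in trained males. Dbp overlapped between non-trained and trained males (43.23 to 80.65 and 65.18 to 97.71 CPM). Per2, Nr1d1 and Dbp are clock genes. A difference in collection time, which the labels do not give, was not tested for that library and stays open. Ide stood at 165.5 to 173.4 CPM in 4 non-trained males, at 331.5 CPM in male non-trained library 5, at 169.9 CPM in male trained library 1 and at 231.9 to 315.8 CPM in the other 4 trained males. In females Ide ran from 172.8 to 263.3 CPM in non-trained and from 147.7 to 278.3 CPM in trained libraries, so it did not separate them by training. These genes were chosen after their values were seen.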
